A study of Homo sapiens with 56 samples.

How the data were processed

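Total RNA of T-HESC cells was taken 48 h after a transfection of 6 h with Silencer Select siRNA at 50 nM, per the labels' protocols, and control cells received a fluorescent BlockIT oligonucleotide. Libraries were made with a TruSeq Stranded Total RNA kit with Ribo-Zero depletion and sequenced on a HiSeq 4000 as single reads of 50 bases. The labels state 3 biological replicates and that libraries with knockdown over 70% by qRT-PCR were chosen. Each of the 28 libraries was sequenced in 2 runs, which carry 1 library name and count as 1 replicate. Per the labels, replicate 2 of CENPT, 3 of FOXF1, 2 of HOXA7 and 3 of STAT5B were left out. For CENPT the notes that name replicate 2 stand beside 1 run of replicate 2 and 1 of replicate 3, so which of its libraries was left out is uncertain. The control group of each knockdown is named there. Control oligonucleotide and siRNA differ in kind, so a comparison holds any effect of carrying an siRNA as well as that of its target.

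The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.6, edgeR, limma and DESeq2 2.11.40.6 and the build hg38. The notes give tools without their order, and the annotation release, counting settings and use of strand are not given in the sources used here. Per the file headers the tables are DESeq2 results for 100454 Ensembl transcripts, 1 table per knockdown. The base mean that the authors deposited is a signal, the mean of normalised counts over the libraries of the comparison. The fold change and its standard error are on the log2 scale per the file headers, and their sign was checked on the targeted genes as knockdown over control. The Wald statistic is a score the authors deposited, the ratio of those 2 values to within rounding. The p-value and adjusted p-value are the authors' own, from DESeq2 with Benjamini-Hochberg adjustment. An adjusted p that the authors' DESeq2 tables leave empty stayed empty. The number of libraries behind each table was checked on its lowest base means, since 1 read in 1 library gives a value set by the number of libraries and that library's size factor. This gave 5 libraries for CENPT, 6 for ERF, 5 for FOXF1, HOXA7, KDM5B and RUNX1T1, and 4 for NR1H3 and STAT5B, the numbers the labels give, so runs did not enter as separate samples. Size factors within a table differed by a ratio of 1.23 (NR1H3) to 1.57 (CENPT). The depth of each library is unknown, and the 10 most abundant transcripts held between 19.4% (FOXF1) and 25.2% (CENPT) of the base mean.

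Transcript names were matched without version to GENCODE release 29 on GRCh38, from which gene symbols and coordinates come. Of 100454 transcripts 83066 (82.7%) matched, 68185 of them with the same version, and 17388 had no match and kept no gene name. A gene stood for its transcript with the highest base mean averaged over the tables. Gene totals were computed by adding the control means and the knockdown means of all transcripts of a gene, with an SE from those of the transcripts taken as independent, and tested with Benjamini-Hochberg adjustment over genes with a base mean of at least 10. Reads that StringTie can share among transcripts make their errors dependent, so the SE of a total is approximate. It is too small where copies share the same reads and too large where transcripts of a gene exchange reads. Of 140 named genes, 46 share exonic bases with another annotated gene, 14 of them on the same strand, and their values are uncertain since the use of strand is not stated. Among these are HAS2 with HAS2-AS1, CEBPB with CEBPB-AS1, HOXA7 with HOXA-AS3, HSPG2 with LDLRAD2, ACAT2 with SOD2 and THBS1 with FSIP1. Ribosomal protein and metallothionein genes have near-identical copies and are uncertain for that reason.

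A transcript was called at the authors' adjusted p under 0.05. Named genes were chosen by a fixed rule. It took the targeted gene, then the 10 genes with the largest rise and the 10 with the largest fall among those called with a base mean of at least 100 and a proper gene symbol. It added up to 4 called members of each gene list with at least 3 called members or a list test past 0.05, and the 10 genes each way that were called in the most tables. Because that rule mostly returned transcripts at nearly no reads in 1 group, a further rule was added after the tables were seen, which took called protein-coding genes whose main transcript held at least 90% of the gene's base mean with an SE of 0.5 or less. From both sets the text describes those that could be said to be known for a function, and TOP2A, MCM3, UHRF1, PTCH1, RNA5-8SN2, HTR2B, CORIN, the members given as adjusted over the list alone, STAT5B after ERF knockdown, and genes compared between knockdowns were named after their values were seen. Fold changes of 5 or more in size are fitted values and no bound on the change.

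The 28 gene lists were written, and the tests, naming rule and most alternatives fixed, before the data were examined. Each list with at least 3 members at a base mean of at least 10 was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed Wald statistic against all other genes, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 208 tests. An estimated correlation was not possible without values per library, so a preset of 0.05 served as the stricter alternative, under which 20 of the 34 calls remained. Overlaps between knockdowns were set beside the product of the numbers called divided by the transcripts tested, and beside 20 simulations per pair of unchanged knockdowns against shared controls. Differences between knockdowns with the same control were tested by a z test whose SE ignores the shared part and is therefore at most too large. Where 2 controls differ, a difference also holds that between the controls.

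To look for action of an siRNA on other messages, all heptamers were counted in the 3′ UTRs of 9655 genes. For each table the log2 fold change of the main transcript, limited to 3 in size, was regressed on the presence of each heptamer with UTR length, GC content and 8 repeat heptamers as covariates, over genes with a base mean of at least 30 and an SE of at most 0.8. Heptamers found in the mRNA of the targeted gene were ranked by z, and the lowest was taken for each table. It was thus chosen by how its carriers fell in that table, so the shares of falling genes that carry it follow in part from the choice and are no separate test. The guide sequences are not given in the sources used here.

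Each step was tested on simulated data. The number of libraries was recovered as 5 of 5 on values drawn after the FOXF1 table (35649 transcripts). With 12018 genes drawn after the ERF table, with errors independent between transcripts, gene totals called 53% of genes changed by log2 1 and 74% of those changed by log2 2, and 0.0338% of 11818 unchanged genes. A heptamer planted in the KDM5B table (7554 genes) ranked 1, and without one the lowest z was −3.99. Unchanged knockdowns made of random normal values for 11000 genes, with the library numbers of KDM5B and RUNX1T1, had a correlation of 0.61 where 0.6 was built in. In 50 sets of random normal values for the 11812 genes of the KDM5B table, independent between genes, 0.154% of list tests passed, and a shifted list ranked 1. With no correlation between genes built in, this cannot show how often the list test passes for unchanged genes that vary together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The alternatives tried were other thresholds, a filter on base mean, no independent filtering, a wider SE, other scalings of the statistic, gene totals and calls without transcripts of size 5 or more. Values for single libraries and for the 4 libraries left out were not analysed here.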

Results

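RNA was sequenced from T-HESC, a line of human endometrial stromal fibroblasts immortalised with telomerase, 48 h after transfection with small interfering RNA (siRNA) against 1 of 8 genes or with a control oligonucleotide. The series asks which genes depend on regulators linked to endometrial gene expression and decidualization, the change of stromal fibroblasts into the secretory cells that support implantation. The targeted genes were CENPT, a protein of the inner kinetochore, ERF, an ETS-family repressor controlled by ERK, FOXF1, a forkhead factor of mesenchyme, HOXA7, a homeobox factor, KDM5B, a demethylase of histone H3 lysine 4, NR1H3, the nuclear receptor LXR alpha, RUNX1T1, the corepressor also called ETO, and STAT5B, a cytokine-activated transcription factor. The labels list 28 libraries, each sequenced in 2 runs, and state that 4 were not used, which leaves 24. The first control group, called control 3 here, had 3 libraries and served CENPT (2 libraries), ERF (3), FOXF1 (2) and HOXA7 (2). The other, called control 4, had 2 libraries and served KDM5B (3), NR1H3 (2), RUNX1T1 (3) and STAT5B (2). The values analysed were the authors' 8 tables of fold changes, 1 per knockdown and 100454 transcripts each, so no spread between libraries could be computed here. Errors given for a transcript are the standard errors (SE) the authors deposited. Those of gene totals, sums over the transcripts of a gene, were computed here from the deposited SE and are approximate. Reads per library are unknown. The base means, which are normalised read counts averaged over the libraries of a comparison, summed to between 9712826 for NR1H3 and 10678241 for RUNX1T1, and 32518 (NR1H3) to 36247 (ERF) transcripts had reads.

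The targeted genes came first. CENPT transcript ENST00000562787.6 (GRCh38 chromosome 16, 67828157 to 67847458) fell by 2.58 ± 0.40 (log2 fold change ± SE, adjusted p = 2.1e-08), to 16.7% of control, in the authors' deposited table for its knockdown. STAT5B (ENST00000293328.8, chromosome 17, 42199168 to 42276406) fell by 3.34 ± 0.46 (adjusted p = 2.8e-10), to 9.85% of control. ERF (ENST00000222329.9, chromosome 19, 42247572 to 42255157) fell by 1.78 ± 0.36 (adjusted p = 1.1e-04), to 29% of control. FOXF1 (ENST00000262426.6, chromosome 16, 86510527 to 86515418) fell by 1.58 ± 0.49 (adjusted p = 0.026), to 33.5% of control. For the other 4 genes the fitted change was negative but did not pass an adjusted p of 0.05 in the authors' deposited tables. HOXA7 (ENST00000242159.5, chromosome 7, 27153716 to 27156677) had a log2 fold change of −5.0 ± 1.81 (adjusted p = 0.18) at a base mean of only 7.69. NR1H3 (ENST00000467728.5, chromosome 11, 47257979 to 47268845) had −3.72 ± 1.56 (adjusted p = 0.35) at a base mean of 17.6. KDM5B (ENST00000367265.9, chromosome 1, 202724495 to 202809470) had −1.65 ± 1.84 (adjusted p = 0.92), and RUNX1T1 (ENST00000613302.4, chromosome 8, 91954967 to 92095654) had −1.13 ± 0.54 (adjusted p = 0.65). The change of KDM5B was smaller than its SE, and those of HOXA7, NR1H3 and RUNX1T1 were above their SE without passing the adjustment over all transcripts. The labels state that libraries were chosen for knockdown of over 70% by qRT-PCR. In the 56 tests of these genes in the other knockdowns, 1 passed, a fall of STAT5B by 0.96 ± 0.29 (adjusted p = 0.049) after ERF knockdown.

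**Figure D1:**
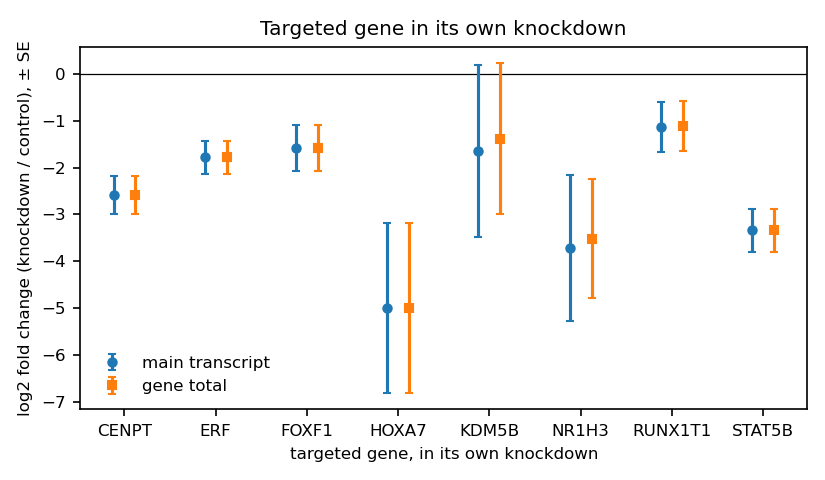
Log2 fold change (knockdown over control, ± SE) of each targeted gene in its own knockdown, for its main transcript (circles) and for the sum over its transcripts (squares). All 8 lie below 0, from −1.13 for RUNX1T1 to −5.0 for HOXA7, and the SE bar of the KDM5B transcript (1.84) crosses 0.

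Across the 8 tables, FOXF1 knockdown changed the most transcripts at an adjusted p under 0.05, 1424 (578 higher, 846 lower), in 1242 genes. The other 7 had 417 (ERF) to 585 (NR1H3) called transcripts. Per knockdown the calls were 459 for CENPT (191 higher, 268 lower), 417 for ERF (182 and 235), 472 for HOXA7 (189 and 283), 565 for KDM5B (312 and 253), 585 for NR1H3 (282 and 303), 452 for RUNX1T1 (252 and 200) and 573 for STAT5B (280 and 293). Many of these were transcripts at nearly no reads in 1 group, for which the authors' deposited tables hold fitted log2 fold changes of 5 or more in size, while other transcripts of the same gene moved the other way. Of 2713 such calls with a gene name, 1867 (68.8%) had a gene total, the sum over all transcripts of the gene, that moved by less than 0.5. Tested as gene totals, the number of changed genes was 696 for FOXF1, 107 for KDM5B, 76 for ERF, 50 for HOXA7, 21 for RUNX1T1, 20 for CENPT, 19 for STAT5B and 13 for NR1H3. Where transcripts exchange reads the SE of a total is too large, so these numbers may be too low. Of the named calls, 50 did not pass as gene totals with the same sign. For 23 of these fold and SE were within 0.1 of those of the transcript and only the adjustment differed, among them ASNS after CENPT (0.87, adjusted p = 0.092), NCAPH after ERF (0.86, 0.075) and CEBPB after HOXA7 knockdown (0.73, 0.074). The genes described first in each account below have 1 main transcript that holds at least 90% of the reads of the gene, a rule added after the tables were seen.

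**Figure D2:**
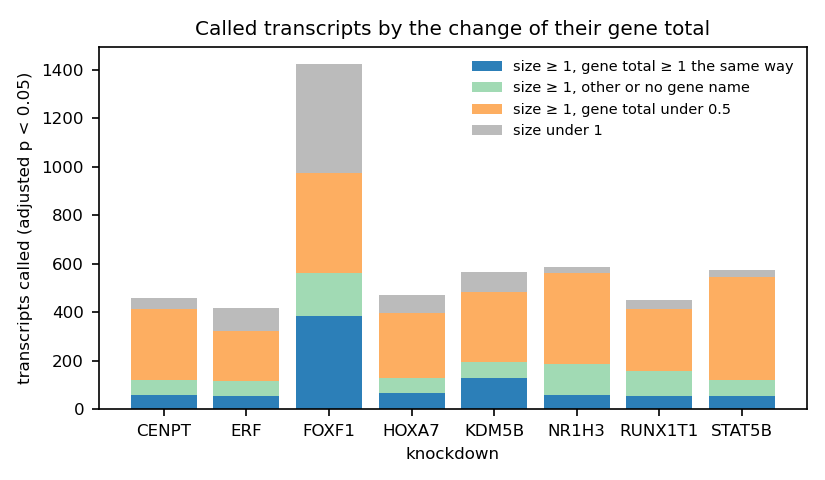
Number of transcripts called at an adjusted p under 0.05 in each knockdown, divided by the size of the transcript's log2 fold change and by the change of its gene total. FOXF1 has 1424 calls, and in STAT5B knockdown 77.7% of the called transcripts of size 1 or more belong to genes whose total moved by less than 0.5.

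After CENPT knockdown, the kinetochore gene DSN1 and the translation control gene EIF4EBP1 fell, and the asparagine synthetase gene ASNS rose. DSN1, a subunit of the MIS12 complex, fell by 1.71 ± 0.41 (adjusted p = 0.0033), EIF4EBP1, which binds the cap-binding factor eIF4E, fell by 1.22 ± 0.27 (adjusted p = 8.6e-04), and SLC2A3, a glucose transporter, fell by 0.93 ± 0.25 (adjusted p = 0.015) in the authors' deposited table. CIAO1, a factor of iron-sulfur cluster assembly, fell by 1.2 ± 0.19, CREBL2 by 1.19 ± 0.21, DERA, a deoxyribose-phosphate aldolase, by 1.44 ± 0.40, and the phosphate exporter gene XPR1 by 1.32 ± 0.38. Rises were fewer, 5 against 20 falls by the single-transcript rule, CENPT itself among the falls. They included ASNS at 0.87 ± 0.23 (adjusted p = 0.014), the chromatin protein gene HMGA2 at 0.71 ± 0.17, GALNT7 at 0.82 ± 0.22, and NRAS at 0.65 ± 0.20 (adjusted p = 0.0495). KRT34, a keratin gene, rose by 1.97 ± 0.59 (adjusted p = 0.0451).

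Of the 24 measured genes of the unfolded protein and integrated stress response, 21 had a positive log2 fold change after CENPT knockdown (median 0.52, list test adjusted p = 4.2e-05). ASNS was called, and adjusted over the list alone 3 were higher, ASNS, the transcription factor gene ATF4 (0.64) and PSAT1 of serine synthesis (0.87). Cytosolic ribosomal protein genes had positive values in 37 of 40 members with none called and 0 adjusted over the list alone (median 0.50, list test adjusted p = 7.2e-05). The 3 measured metallothionein genes, with none called and 0 adjusted over the list alone, had a median of 1.08 (list test adjusted p = 0.0485), a call lost at adjusted p = 0.094 with a preset correlation of 0.05. The centromere and kinetochore list as a whole did not pass (adjusted p = 0.96). Large fitted falls included transcripts of RPS17 (−12.24), MME (−11.39) and RBFOX2 (−10.93) in the authors' deposited table, for genes whose totals were 0.46, −0.31 and −9.32. Of the 11 named genes that fell, 5 carried the heptamer GAGAGGA in their 3′ UTR, among them DSN1, CIAO1 and EIF4EBP1, against 0 of 6 named genes searched that rose. The heptamer occurs in the CENPT mRNA but also in those of ERF, KDM5B, NR1H3, RUNX1T1 and STAT5B, and 16.8% of all genes searched carried it.

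ERF knockdown lowered THBS1 and DOCK4 and raised the cell cycle regulator gene MYBL2. THBS1, the matrix glycoprotein thrombospondin 1, fell by 1.83 ± 0.43 (adjusted p = 0.002), DOCK4, an activator of Rac, by 1.80 ± 0.36 (adjusted p = 8.1e-05), and YWHAG, a 14-3-3 protein gene, by 1.75 ± 0.24 (adjusted p = 3.2e-10) in the authors' deposited table. ARL5B, a small GTPase gene, fell by 1.49 ± 0.18 (adjusted p = 3.7e-13), SFXN1, a mitochondrial serine carrier, by 1.40 ± 0.19, the secreted guidance factor gene SEMA3C by 1.09 ± 0.25, and SCUBE3 by 1.34 ± 0.33. MYBL2, a transcription factor of dividing cells, rose by 1.68 ± 0.39 (adjusted p = 0.0018), the condensin gene NCAPH by 0.86 ± 0.25 (adjusted p = 0.037), the histone gene HIST1H2AL by 0.89 ± 0.26 (adjusted p = 0.045) and UCK2, a uridine-cytidine kinase, by 1.13 ± 0.30. PPIF, cyclophilin D of mitochondria, rose by 0.77 ± 0.19.

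Cell cycle lists stood higher than other genes after ERF knockdown, although none of their members was called higher. Of 30 cell division genes 27 had positive values and none was called (median 0.51, list test adjusted p = 8.6e-06). Adjusted over the list alone 3 were higher, CCNB1 (0.69), CCNB2 (0.78) and the kinase gene PLK1 (0.94). Of 30 S phase genes 24 were positive (median 0.39, list test adjusted p = 1.5e-04), with RRM2 called lower for its main transcript (−5.83) while its gene total was 0.34. Adjusted over the list alone, 2 S phase genes were higher and 1 lower. The 25 centromere and kinetochore genes had a median of 0.29 (adjusted p = 0.0013, none called, 0 adjusted over the list alone). The 40 ribosomal protein genes had a median of 0.39 (adjusted p = 5.7e-05, none called, 0 adjusted over the list alone). Extracellular matrix genes did not pass after ERF knockdown (33 measured, median −0.32, adjusted p = 0.065), with 1 called lower and 1 lower adjusted over the list alone. ERK-responsive genes did not pass in this or any other knockdown, the smallest adjusted p being 0.13 for KDM5B. Among the 13 named genes that fell, 10 carried ATCAGTG in the 3′ UTR, among them THBS1, DOCK4, YWHAG, ARL5B and STAT5B, against 14.1% of all genes searched. This heptamer occurs in the ERF mRNA and also in those of KDM5B and STAT5B.

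FOXF1 knockdown lowered 9 of 25 measured cholesterol biosynthesis genes and 4 of 12 NF-kB target genes and raised 7 of 24 p53 targets and 2 of 3 metallothionein genes. The NF-kB list test was lost with a preset correlation of 0.05. RNA5-8SN2, a ribosomal RNA gene, was also called lower in this knockdown (−3.45 ± 1.09), and RNA quality was not tested as an explanation. CCL2, a chemokine that attracts monocytes, fell by 2.26 ± 0.50 (adjusted p = 2.5e-04), SEMA3A, a secreted guidance factor, by 2.50 ± 0.30 (adjusted p = 8.5e-15), FABP3, a fatty acid binding protein gene, by 2.59 ± 0.44 (adjusted p = 3.4e-07), and ANLN, the cytokinesis protein anillin, by 2.44 ± 0.45 (adjusted p = 4.2e-06) in the authors' deposited table. HYOU1, a chaperone of the endoplasmic reticulum, fell by 5.25 ± 0.35 (adjusted p = 5.3e-48). GDF15, a stress-induced cytokine and p53 target, rose by 1.89 ± 0.19 (adjusted p = 3.4e-21), the cell cycle inhibitor gene CDKN1A by 1.31 ± 0.20 (adjusted p = 4.0e-09), haem oxygenase HMOX1 by 1.46 ± 0.46 (adjusted p = 0.033), and the lysosomal transporter gene ATP13A2 by 2.32 ± 0.35. The single-transcript rule gave 341 falls and 158 rises.

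Of 24 p53 target genes, 7 rose after FOXF1 knockdown and none fell (median 0.32, list test adjusted p = 1.8e-04). Among the 7 were GDF15, CDKN1A, the growth inhibitor gene BTG2 (1.89 ± 0.36) and MDM2, the ubiquitin ligase of p53 (0.70 ± 0.11), and 7 were higher and 1 lower adjusted over the list alone. Cholesterol biosynthesis genes were lower in 21 of 25 members, with 9 called lower (median −0.81, list test adjusted p = 4.0e-06) and 12 lower and 1 higher adjusted over the list alone. Examples were the sterol oxidase gene MSMO1 (−1.93 ± 0.33), the thiolase gene ACAT2 (−1.14 ± 0.23), the sterol isomerase gene EBP (−0.92 ± 0.15) and the demethylase gene CYP51A1 (−0.77 ± 0.14). Of 12 NF-kB target and cytokine genes measured, 4 fell, CCL2, RELB (−1.92 ± 0.30), BIRC3 (−2.04 ± 0.39) and the inhibitor gene NFKBIA (−0.65 ± 0.19), and the same number were lower adjusted over the list alone. That list's test had an adjusted p of 0.045 (median −0.33), and adjusted p = 0.17 with the correlation of 0.05. A further alternative gave a higher value still, so the loss is not tied to the correlation alone. Of 3 measured metallothionein genes, MT1E (1.37 ± 0.18) and MT2A (0.94 ± 0.29) rose, also adjusted over the list alone, 2 in number (median 1.37, list test adjusted p = 8.2e-04).

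S phase genes had 5 members lower and 1 higher after FOXF1 knockdown, and 7 lower and 1 higher adjusted over the list alone, with no list test passed (adjusted p = 0.14). The member called higher, UHRF1 (3.57), had a gene total of −0.69, and 1 called lower, MCM3 (−2.27), a gene total of 0.11. CLSPN, a checkpoint adaptor, fell by 0.96 ± 0.14 (adjusted p = 1.2e-09) in the authors' deposited table, and GINS1, of the replicative helicase, fell as well (adjusted p = 3.8e-06). Stress response genes had 4 members higher, and 5 adjusted over the list alone, among them TRIB3 (0.89 ± 0.23), ASNS (0.70 ± 0.20) and DDIT4 (1.27 ± 0.36), again without passing as a list (adjusted p = 0.14). The hedgehog and forkhead mesenchyme list did not pass (adjusted p = 0.70), with 1 of 15 members, PTCH1 (−6.65, gene total −0.6), called lower and 1 adjusted over the list alone. The robust spread of the statistic over well-expressed transcripts was 1.2 here, above the 1 expected of unchanged genes, and with the statistic divided by it 811 transcripts were called. In the 3′ UTR of 10 of 24 named genes searched that fell lay TGTCTTC, against 2 of 20 that rose and 19.8% of all genes searched. SEMA3A, ANLN, UHMK1, DESI2 and MSMO1 carried it and CCL2, HYOU1 and FABP3 did not. Related heptamers such as GTCTTCA were not looked for in the named genes.

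After HOXA7 knockdown, the hyaluronan synthase gene HAS2 and the checkpoint ligand gene PDCD1LG2 fell and the integrated stress response gene TRIB3 rose. HAS2 fell by 1.74 ± 0.23 (adjusted p = 1.7e-11), PDCD1LG2, which encodes the PD-1 ligand PD-L2, by 1.27 ± 0.27 (adjusted p = 3.1e-04), the cation channel gene TRPC6 by 1.34 ± 0.30 (adjusted p = 9.9e-04) and WDR26 by 3.26 ± 0.36 (adjusted p = 2.7e-16) in the authors' deposited table. BICC1, an RNA-binding protein gene, fell by 1.42 ± 0.29, SLC9A7, a sodium-proton exchanger of the trans-Golgi, by 1.35 ± 0.25, and KPNA1, a nuclear import receptor, by 1.18 ± 0.25. GDF15 rose by 1.72 ± 0.24 (adjusted p = 4.0e-10), TRIB3, a pseudokinase induced by ATF4, by 1.23 ± 0.26 (adjusted p = 1.9e-04), the surface protein gene LY6E by 1.06 ± 0.30, CEBPB, a transcription factor used in decidualization, by 0.73 ± 0.21 (adjusted p = 0.021), and NRAS by 0.63 ± 0.15. SQSTM1, an autophagy receptor gene, rose by 3.05 ± 0.32, with a gene total of 1.2.

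Stress response genes were higher as a list after HOXA7 knockdown (24 measured, median 0.66, list test adjusted p = 8.2e-04). TRIB3 and the low-expressed ATF5 (3.29 ± 0.97, base mean 11.2, gene total 0.76) were called, and the count was also 2 adjusted over the list alone. Mitochondrially encoded genes were lower in 12 of 13 members (median −0.71, adjusted p = 2.7e-04, and adjusted p = 0.059 with a base mean of at least 100), with MT-ATP6 called (fitted −6.23 ± 1.02, base mean 59.8) and 2 lower adjusted over the list alone. HOX genes had 11 of 15 positive values, none called and 0 adjusted over the list alone (median 0.41, adjusted p = 0.017, and adjusted p = 0.099 with a preset correlation of 0.05). NF-kB target genes had a median of 0.47 over 12 members, none called and 0 adjusted over the list alone (adjusted p = 0.044, and adjusted p = 0.17 with the correlation of 0.05). Ribosomal protein genes had a median of 0.30 over 40 members (adjusted p = 0.0485, and adjusted p = 0.3 with that correlation), with RPS2 called lower, also adjusted over the list alone (1), at a fitted −3.77 and a gene total of 0.01. AGGACGA, a heptamer of the HOXA7 mRNA, lay in the 3′ UTR of 2 of 9 named falling genes searched, SLC9A7 and KPNA1, and in 2.1% of all genes searched.

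KDM5B knockdown lowered genes of DNA replication and cell division. Its extracellular matrix list stood higher, as it did in the other 3 knockdowns set against control 4, of which RUNX1T1 (adjusted p = 0.2) and STAT5B (0.23) did not pass with a preset correlation of 0.05. E2F1, a transcription factor of S phase entry, fell by 1.54 ± 0.33 (adjusted p = 3.4e-04), the flap endonuclease gene FEN1 by 1.17 ± 0.24 (adjusted p = 1.9e-04), the cohesin acetyltransferase gene ESCO2 by 1.47 ± 0.25 (adjusted p = 8.5e-07), and HJURP, which loads the centromeric histone, by 1.43 ± 0.31 (adjusted p = 4.8e-04) in the authors' deposited table. CENPA, that histone, fell by 1.25 ± 0.35 (adjusted p = 0.02), the cytokine gene PTN by 1.81 ± 0.34 (adjusted p = 2.3e-05) and MNAT1, a partner of the kinase CDK7, by 1.86 ± 0.24 (adjusted p = 1.3e-11). IGFBP5, which binds insulin-like growth factors, rose by 1.57 ± 0.43 (adjusted p = 0.015), NPTX1, a pentraxin gene, by 2.39 ± 0.45 (adjusted p = 1.5e-05), the basement membrane proteoglycan gene HSPG2 by 1.31 ± 0.34 (adjusted p = 0.0078) and SLC35E1 by 3.12 ± 0.34. BMP2, a morphogen of decidualization, rose by 0.77 ± 0.21 (adjusted p = 0.01).

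Of 30 cell division genes, 29 had negative values after KDM5B knockdown and 5 were called lower (median −1.03, list test adjusted p = 7.7e-13), CCNB1 (−1.16 ± 0.32), CCNF (−0.90 ± 0.24), ECT2 (−0.88 ± 0.26), NUF2 (−1.63 ± 0.48) and TOP2A (−0.88), with 13 lower adjusted over the list alone. Of 30 S phase genes, 29 were negative and 6 called lower (median −0.92, adjusted p = 7.7e-13), among them RRM1 (−0.72 ± 0.16) and CDC45 (−2.13 ± 0.47), with 9 lower adjusted over the list alone. Of 25 centromere and kinetochore genes, 3 were called lower and 1 higher (median −1.12, adjusted p = 8.1e-06), and 9 were lower and 1 higher adjusted over the list alone. The member called higher, CENPL, had 1.82 ± 0.34 for its main transcript and −0.63 for its gene total, and SPC25 had a fitted −6.78 at a base mean of 14.4. Of 33 extracellular matrix genes 30 were positive (median 0.67, adjusted p = 9.2e-06). COL1A1 (0.88 ± 0.23) and COL5A1 (4.99 ± 1.5, gene total 0.92 ± 1.05) were called and 4 were higher adjusted over the list alone.

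Among 12 measured H3K4 demethylase and methyltransferase genes, KDM1A and SETD1B (1.39 ± 0.37) were called higher after KDM5B knockdown (median 0.58, list test adjusted p = 1.8e-04), with 3 higher adjusted over the list alone. The KDM1A value was a fitted 11.16 for a transcript, while the gene total was 0.12. Decidualization genes had BMP2 and IGFBP5 called higher among 27 (median 0.33, adjusted p = 0.04, and adjusted p = 0.23 with a preset correlation of 0.05), with 3 higher and 2 lower adjusted over the list alone. For p53 targets, with BTG2 called (1.91 ± 0.46) and 1 adjusted over the list alone, the values were similar (24 measured, median 0.19, adjusted p = 0.04, and adjusted p = 0.23 with that correlation). KDM5B mRNA itself did not pass its test, so these changes are those of the libraries labelled KDM5B knockdown. GACTTAT, present in the KDM5B mRNA, lay in the 3′ UTR of 3 of 15 named falling genes searched, MNAT1, PTN and ARL5B, against 7.72% of all genes searched.

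NR1H3 knockdown gave no called gene with a single main transcript and a small error. Few transcripts had an SE of 0.5 or less in this knockdown. Pairs of knockdowns could be correlated under that limit over 837 transcripts for KDM5B and NR1H3, against 4166 for KDM5B and RUNX1T1 and 3828 for KDM5B and STAT5B. Both NR1H3 and STAT5B knockdown had 2 libraries against 2, so the number of libraries alone does not account for the wide errors of NR1H3. With so few precise transcripts, the absence of such genes is no measure of a small response. Its called transcripts were mostly fitted at nearly no reads in 1 group, as in the authors' deposited table for NR3C1, the glucocorticoid receptor gene (−11.41), ZEB1, a repressor of epithelial genes (11.32), and KDM1A (10.94). The gene totals computed here were 0.02 ± 1.07 for NR3C1, 0.01 ± 1.07 for ZEB1 and 0.06 ± 0.92 for KDM1A, errors too wide to tell whether the genes as a whole changed. MPRIP, which binds myosin phosphatase, rose by 4.86 ± 0.60 with a gene total of 3.64. KCNK2, a potassium channel gene, rose by 3.56 ± 0.61 with a gene total of 0.97, and SKIL, a repressor of TGF-beta signalling, fell by 6.69 ± 0.57 with a gene total of −0.45. LXR target genes did not pass in this knockdown or another, the smallest adjusted p being 0.11 for RUNX1T1.

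Lists of structural genes stood higher after NR1H3 knockdown with no member called and 0 adjusted over the list alone. Extracellular matrix genes were positive in 26 of 33 (median 0.81, list test adjusted p = 8.2e-04), actin and myofibroblast genes in 15 of 15 (median 0.70, adjusted p = 0.0048), and mitochondrially encoded genes in 13 of 13 (median 0.84, adjusted p = 9.6e-04). Targets of YAP and TEAD were positive in 17 of 19 (median 0.58, adjusted p = 0.0085, and adjusted p = 0.084 with a preset correlation of 0.05). Ribosomal protein genes were negative in 35 of 40 with none called and 0 adjusted over the list alone (median −0.32, adjusted p = 0.04, and adjusted p = 0.27 with that correlation). The H3K4 list (12 measured, median 0.93, adjusted p = 7.6e-05) had KDM1A called higher, as 1 also adjusted over the list alone. NR1H3 mRNA was itself not called at its low read number, and of the 2 named genes that fell none carried the heptamer AAACTGG of its mRNA.

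After RUNX1T1 knockdown, the decoy receptor gene TNFRSF11B and the lipid enzyme genes ELOVL4 and KDSR fell, and the glucose-responsive genes TXNIP and ARRDC4 rose. TNFRSF11B, which encodes osteoprotegerin, fell by 1.65 ± 0.43 (adjusted p = 0.011), ELOVL4, a fatty acid elongase gene, by 1.49 ± 0.35 (adjusted p = 0.0024), KDSR, of sphingolipid synthesis, by 0.94 ± 0.22 (adjusted p = 0.0015), and the cytochrome gene CYP2U1 by 1.21 ± 0.23 (adjusted p = 2.7e-05) in the authors' deposited table. FAM120B fell by 2.42 ± 0.48 (adjusted p = 8.4e-05). TXNIP, a thioredoxin inhibitor, rose by 0.96 ± 0.26 (adjusted p = 0.012), the arrestin gene ARRDC4 by 0.84 ± 0.23 (adjusted p = 0.017), the microRNA-processing gene DICER1 by 0.95 ± 0.25 (adjusted p = 0.011), CDK6, a kinase of the G1 phase, by 0.68 ± 0.20 (adjusted p = 0.039), and SLC35E1 by 2.94 ± 0.39. SLC35E1 also rose after KDM5B knockdown (3.12 ± 0.34), which has the same control. By the single-transcript rule 18 genes fell and 7 rose. As gene totals TNFRSF11B (adjusted p = 0.069), TXNIP (0.1), ARRDC4 (0.097), DICER1 (0.074) and CDK6 (0.14) did not pass, at folds within 0.1 of those given and under another adjustment.

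Of 30 cell division genes, 24 had positive values after RUNX1T1 knockdown, none called (median 0.37, list test adjusted p = 0.0012, and adjusted p = 0.0502 with a preset correlation of 0.05), and CCNB2 (0.55) and PLK1 (2.55) were the 2 higher adjusted over the list alone. Extracellular matrix genes were positive in 26 of 33 (median 0.50, adjusted p = 0.017, and adjusted p = 0.2 with that correlation), yet the 1 member called, the collagen crosslinking enzyme gene LOX, fell by 0.76 ± 0.22, as it did adjusted over the list alone (1). HOX genes were positive in 13 of 13 with none called and 0 adjusted over the list alone (median 0.33, adjusted p = 0.042, and adjusted p = 0.17 with that correlation). Ribosomal protein genes were negative in 34 of 40 with none called and 0 adjusted over the list alone (median −0.34, adjusted p = 0.022, and adjusted p = 0.23 with that correlation). The RUNX, CBF and ETO family list did not pass in any knockdown (smallest adjusted p = 0.43, NR1H3). RUNX1T1 mRNA did not pass its own test, and ATCCCAT, found in it, lay in the 3′ UTR of 4 of 8 named genes that fell, including TNFRSF11B, KDSR and LOX, of 2 of 6 searched that rose, and of 10.6% of all genes searched.

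STAT5B knockdown lowered its target to 9.85% of control with few other single-transcript changes, 2 falls and 2 rises. With 2 libraries against 2, the robust spread of the statistic over well-expressed transcripts was 0.56, below the 1 expected of unchanged genes. Few calls are therefore no measure of a small response. Besides STAT5B, ARL5B fell by 1.32 ± 0.29 (adjusted p = 5.7e-04) and FAM120B by 1.71 ± 0.50 (adjusted p = 0.027), and MPRIP rose by 4.59 ± 0.43 (adjusted p = 1.4e-22) and EBPL, related to the sterol isomerase EBP, by 2.14 ± 0.41 (adjusted p = 2.0e-05) in the authors' deposited table. MPRIP was called higher after NR1H3 and RUNX1T1 knockdown too, and EBPL after KDM5B knockdown, all set against control 4. COL5A1, a fibrillar collagen gene, was called higher at a fitted 5.22 ± 0.66, with a gene total of 0.56. Extracellular matrix genes had positive values in 23 of 33, with COL5A1 the 1 called and the 1 adjusted over the list alone (median 0.19, list test adjusted p = 0.036, and adjusted p = 0.23 with a preset correlation of 0.05). STAT5 target genes did not pass in this knockdown or another (smallest adjusted p = 0.099, RUNX1T1). Transcripts of the chromosome condensation gene SMC4 (−11.9) and of STAT6 (−10.73) were called at gene totals of 0.1 and −0.05. TTACCTT, a heptamer of the STAT5B mRNA, lay in the 3′ UTRs of ARL5B and FAM120B, 2 of 4 named genes that fell, of 1 of 4 that rose, and of 16.8% of all genes searched.

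**Figure D3:**
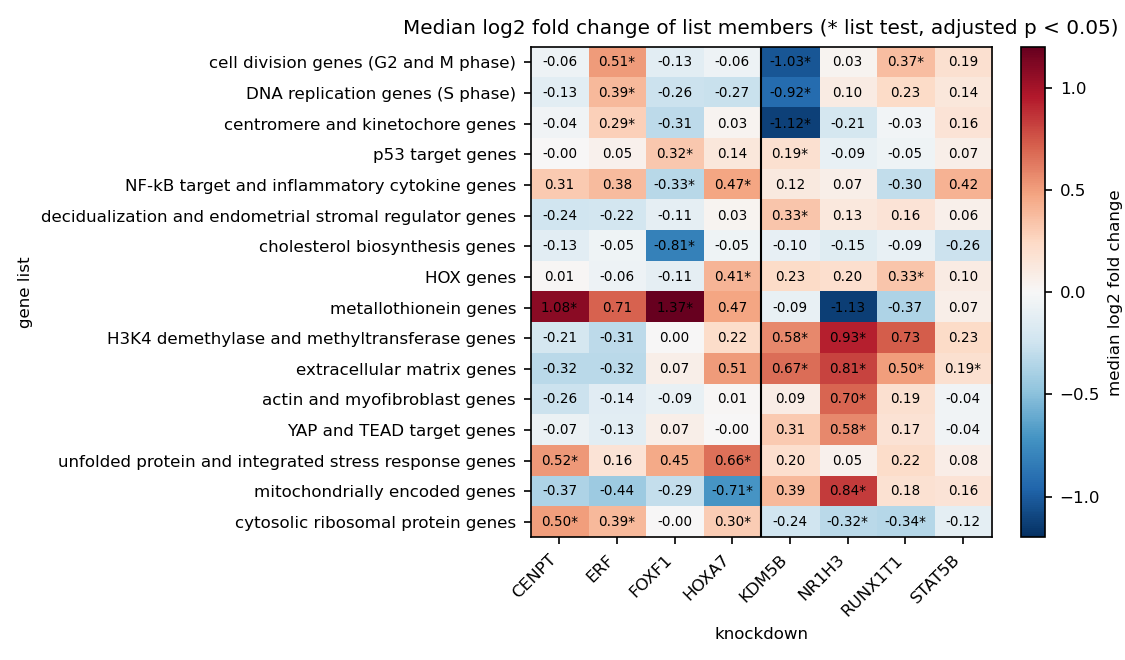
Median log2 fold change (knockdown over control) of the measured members of each gene list past an adjusted p of 0.05 in at least 1 knockdown, as colour and number, with a star where the list test passed and a line between knockdowns set against control 3 (left) and control 4 (right). Cell division genes have a median of −1.03 after KDM5B and 0.51 after ERF knockdown, and cholesterol biosynthesis genes −0.81 after FOXF1 knockdown.

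The medians of some lists are given by control group, a comparison that was not tested. The median of mitochondrially encoded genes lay between −0.71 and −0.29 in the 4 knockdowns set against control 3 and between 0.16 and 0.84 in the 4 set against control 4. For extracellular matrix genes the medians overlapped, −0.32 to 0.51 against control 3 and 0.19 to 0.81 against control 4. Ribosomal protein genes, whose reads can also come from near-identical copies, had medians from 0.00 to 0.50 against control 3 and from −0.34 to −0.12 against control 4. RNA5-8SN2, a gene of 5.8S ribosomal RNA, which the depletion step removes, fell by 3.45 ± 1.09 (adjusted p = 0.033) after FOXF1 knockdown in the authors' deposited table. Its −2.21 ± 1.46 after KDM5B, −2.1 ± 0.96 after ERF and 2.0 ± 1.22 after HOXA7 knockdown did not pass (adjusted p = 0.72, 0.49 and 0.75). Each of its 7 transcripts held close to 14.3% of its reads, as near-identical copies do, so a gene total that takes them as independent has too small an SE and is not used. In all, 34 of 208 list tests passed, 26 toward higher and 8 toward lower values. Lists of interferon-stimulated genes (smallest adjusted p = 0.056, HOXA7), TGF-beta and BMP targets (0.068, NR1H3), hypoxia-response genes (0.55, NR1H3) and the hedgehog list (0.12, NR1H3) passed in no knockdown. Of markers for other cell types, 3 of 14 epithelial genes were measured (smallest adjusted p = 0.27, FOXF1), 2 of 11 endothelial genes, and at most 1 of 12 leukocyte genes, too few for a test.

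Knockdowns that shared a control also shared calls. Summed over the 12 pairs with the same control, 550 calls were higher in both and 599 lower in both, a transcript counting anew in each pair. Independent lists would give sums of 23.93 and 57.56. Unchanged knockdowns simulated against a shared control gave a mean of at most 1.95 shared calls in any single pair, both directions together. Unchanged knockdowns have few calls to share, so that value cannot tell how far shared controls raise the overlap. The same sums over the 16 pairs with different controls were 79 higher and 112 lower, against 46.13 and 64.26. In these pairs 176 calls went opposite ways, against 34 in pairs with the same control, and correlations ran from −0.42 to 0.34. The excess over independent lists is therefore not one of agreement alone. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.19 to 0.53 for pairs with the same control, where the simulation gave 0.38 to 0.57, and the median covariance was 0.0414 against a simulated 0.0518. Part of the excess of shared calls may come from the shared controls, which could not be split because the tables hold no values per library. MIR100HG, a long noncoding RNA that hosts microRNA genes, was called higher in 6 knockdowns under both controls, from 3.81 ± 0.50 (RUNX1T1) to 4.94 ± 0.47 (HOXA7) for its main transcript in the authors' deposited tables. Its gene totals lay between 1.14 (RUNX1T1) and 2.2 (HOXA7), and none of the 6 passed (smallest adjusted p = 0.063, CENPT). TMTC1, an O-mannosyltransferase of the endoplasmic reticulum, fell in 4, by 1.76 ± 0.16 after FOXF1, 1.05 ± 0.28 after RUNX1T1, 0.94 ± 0.24 after ERF and 0.59 ± 0.15 after HOXA7 knockdown. CHD9, a chromatin remodeller gene, was lower in all 4 knockdowns of control 3 and FOXO3, a forkhead factor of stress resistance, higher in all 4 of control 4, each at a transcript fitted near 10 in size or above, with gene totals for CHD9 of −0.37 to −0.03 (adjusted p = 1 in each) and for FOXO3 of −0.32 to 0.56.

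Genes of serotonin, PD-1 ligand and natriuretic signalling formed a list fixed for the maternal-fetal setting, of which 5 to 8 of 13 members were measured and which passed in no knockdown (smallest adjusted p = 0.099, RUNX1T1). Of its members, HTR2B and CORIN are described because their values were seen, while PDCD1LG2 fell under the naming rule. HTR2B (ENST00000258400.4, chromosome 2, 231108230 to 231125118), a serotonin receptor gene, rose by 0.50 ± 0.13 (adjusted p = 0.0085) after KDM5B knockdown in the authors' deposited table, and its fitted 0.78 after HOXA7 and 0.74 after CENPT knockdown did not pass (adjusted p = 0.64 and 0.19). Reads of HTR2B cannot be told from those of PSMD1, with which it shares 559 exonic bases on the opposite strand, as the use of strand in counting is not stated. PDCD1LG2 (ENST00000397747.5, chromosome 9, 5510570 to 5571254) fell after HOXA7 knockdown, by 1.27 ± 0.27, and lay between −0.25 and 0.50 without a call in the other 7. CORIN (ENST00000273857.9, chromosome 4, 47593998 to 47837949), the protease that activates natriuretic peptides, fell by 1.82 ± 0.58 (adjusted p = 0.033) after FOXF1 knockdown, and its −1.63 after CENPT and −1.44 after ERF knockdown did not pass. Against the other 3 knockdowns of its control, HTR2B after KDM5B knockdown did not differ (z test of the difference, adjusted p = 1 in each), nor did CORIN after FOXF1 knockdown (adjusted p = 1 in each), while PDCD1LG2 after HOXA7 knockdown differed by −1.38 from FOXF1 knockdown (adjusted p = 0.0485) without passing against CENPT (adjusted p = 0.21) or ERF (adjusted p = 0.16).

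**Figure D4:**
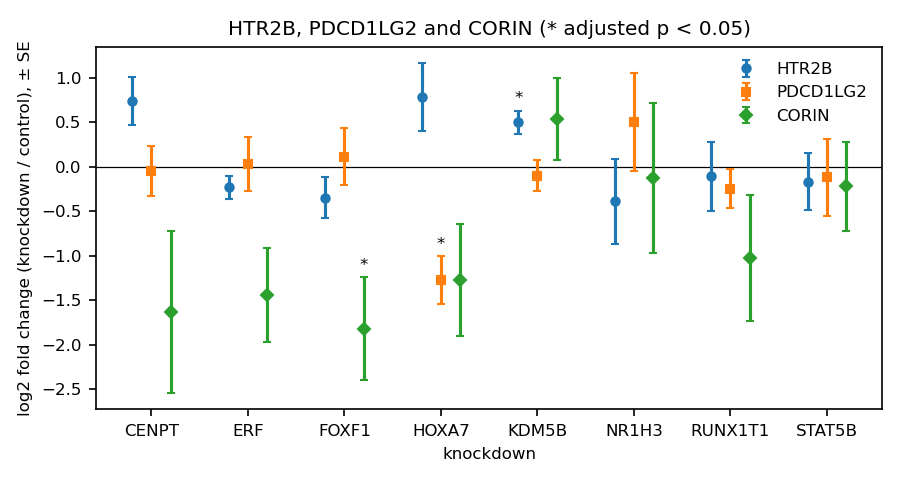
Log2 fold change (knockdown over control, ± SE) of HTR2B, PDCD1LG2 and CORIN in each of the 8 knockdowns, with a star where the adjusted p is under 0.05. Calls are HTR2B after KDM5B (0.50), PDCD1LG2 after HOXA7 (−1.27) and CORIN after FOXF1 (−1.82), and the SE bars of CORIN are the widest of the 3 in most knockdowns.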

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

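The differences of lists between knockdowns, the lists by gene totals or without heptamer genes and the tests of explanations were chosen after the results they concern had been seen. The z tests between knockdowns of the same control and the lists with a preset correlation of 0.05, with ranks and with a base mean of at least 100 were planned. The results here are genes and gene lists that went opposite ways, each past its threshold, in 2 knockdowns, and whose difference passed a test of its own. Of 728 comparisons of a list between 2 knockdowns 150 passed an adjusted p of 0.05, and 12 of these were called in opposite directions.

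The cell division list was lower after KDM5B and higher after ERF knockdown (medians −1.03 and 0.51, adjusted p of the difference = 5.8e-15), as was the S phase list (−0.92 and 0.39, 8.8e-13) and the centromere and kinetochore list (−1.12 and 0.29, 1.2e-07), and KDM5B also differed from RUNX1T1 knockdown in the cell division list (−1.03 and 0.37, 1.4e-26). For RUNX1T1 the call of the list was lost with a preset correlation of 0.05 (0.0502, other alternatives 1.9e-04 to 0.0039). A different growth state of the shared control libraries argues for a shift common to their knockdowns. This was judged on the cell division list alone, in which KDM5B knockdown differed from each of the other 3 set against control 4 (largest adjusted p = 9.1e-10), and ERF knockdown from each of the other 3 set against control 3 (largest adjusted p = 0.004). These differences were not tested with the preset correlation of 0.05, and their p-values weigh spread across genes and not between libraries. They argue against a common shift without excluding it, more weakly for ERF. Sites of the heptamer taken for each table, in the 3′ UTR of the main transcript, do not alone account for the shifts. Without genes that carry that heptamer the cell division list (adjusted p = 5.5e-13 for KDM5B and 2.5e-05 for ERF), the S phase list (1.5e-12 and 1.9e-04) and the centromere list (2.7e-05 and 0.0013) passed. Other sites of the siRNA in list members could not be searched, as the guide sequences are not given, so its direct action on members stays open. An siRNA guide acting on a regulator cannot be told apart from an effect of the intended target, because siRNA and target go together in these tables and MNAT1, a partner of CDK7 with the heptamer in its 3′ UTR, fell after KDM5B knockdown (−1.86). RNA quality was not tested as an explanation, and the residual ribosomal RNA of RNA5-8SN2 had the same sign after both knockdowns (−2.21 ± 1.46 and −2.1 ± 0.96) without passing. For the S phase and centromere lists the growth state of the controls stays open, since their differences within a control group were not examined for it. Loss of KDM5B or ERF itself stays open and was not tested, and KDM5B mRNA did not pass its own test.

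The ribosomal protein list was higher after CENPT, ERF and HOXA7 knockdown and lower after NR1H3 and RUNX1T1 knockdown. The adjusted p of the difference was 1.3e-05 for CENPT against NR1H3 (medians 0.50 and −0.32), 1.9e-06 for CENPT against RUNX1T1 (0.50 and −0.34), 1.1e-05 for ERF against NR1H3 (0.39 and −0.32), 9.1e-08 for ERF against RUNX1T1 (0.39 and −0.34), 0.0013 for HOXA7 against NR1H3 (0.30 and −0.32) and 3.2e-05 for HOXA7 against RUNX1T1 (0.30 and −0.34). Over the alternatives the adjusted p of the list itself ran from 0.0034 to 0.3 for HOXA7, 2.1e-04 to 0.27 for NR1H3 and 5.7e-04 to 0.23 for RUNX1T1, the highest with a preset correlation of 0.05, so these 3 calls depend on it, and that for NR1H3 was also lost without heptamer genes (0.0509). For CENPT and ERF the highest were 0.018 and 0.016. Mitochondrially encoded genes were lower after HOXA7 and higher after NR1H3 knockdown (−0.71 and 0.84, adjusted p = 1.9e-07), although the HOXA7 call was lost with a base mean of at least 100 (adjusted p 0.059, others 1.0e-06 to 0.0062). Each of these 7 pairs joins knockdowns with different controls, so the difference between the control groups is part of them. NF-kB target genes were lower after FOXF1 and higher after HOXA7 knockdown, which share a control (−0.33 and 0.47, adjusted p = 1.6e-04). Both calls were lost with the correlation of 0.05 (adjusted p = 0.17 each), over alternatives that gave 0.0042 to 0.27 for FOXF1 and 0.04 to 0.17 for HOXA7, and no member was called after HOXA7 knockdown.

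Single genes are given here for knockdowns of the same control and main transcripts with at least 90% of the gene's reads, since with different controls a difference also holds that between the controls. The 9 such comparisons all involved FOXF1 knockdown. NRAS rose after CENPT and fell after FOXF1 knockdown (0.65 and −0.99, z of the difference 5.83, adjusted p = 1.4e-06), and rose after HOXA7 knockdown (0.63, z of FOXF1 minus HOXA7 −6.48, adjusted p = 2.6e-08). GALNT7 went the same ways for CENPT and FOXF1 (0.82 and −1.19, z 7.32, adjusted p = 1.7e-10). CREBL2 fell after CENPT and rose after FOXF1 knockdown (−1.19 and 0.37, z −6.73, adjusted p = 7.4e-09), as did EIF4EBP1 (−1.22 and 0.94, z −6.26, adjusted p = 1.3e-07). For ERF against FOXF1, SFXN1 (−1.40 and 0.76, z −7.53, adjusted p = 4.1e-11), XPNPEP1 (−0.67 and 0.46, z −5.61, adjusted p = 4.7e-06) and ELOVL4 (−0.72 and 0.76, z −6.96, adjusted p = 1.9e-09) fell after ERF and rose after FOXF1 knockdown, and PPP2R1B did the reverse (0.59 and −0.77, z 6.33, adjusted p = 9.3e-08). In each of these 9 comparisons the gene carried, in its 3′ UTR, the heptamer of the knockdown in which it fell, except CREBL2 after CENPT knockdown, and the choice of each heptamer by the falls of its table favours this.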

How the results depend on the processing

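Gene totals, calls without transcripts of size 5 or more, and lists by gene totals or without genes carrying the heptamer were chosen after the data were seen. No paired analysis was possible because the tables hold no values per library, and for that reason leaving out each replicate, other splits of the samples, refits from counts, the libraries left out by the labels and an estimated correlation between genes were not run. With a size of at least 1, a base mean of at least 10, no independent filtering or centred fold changes, all 8 counts of calls stayed within 1.5 times. With the SE multiplied by the square root of 2, meant for runs entered as separate samples, which the check on libraries argues against, the counts were 163 (CENPT), 133 (ERF), 513 (FOXF1), 172 (HOXA7), 167 (KDM5B), 173 (NR1H3), 125 (RUNX1T1) and 205 (STAT5B), and ERF (−1.78, adjusted p = 0.071) and FOXF1 (−1.58, adjusted p = 0.49) no longer passed in their own knockdowns, since only the error grew. As gene totals the counts were 20, 76, 696, 50, 107, 13, 21 and 19 in the same order, with 30% higher for CENPT, 21.1% for ERF, 69.2% for NR1H3 and 36.8% for STAT5B against 41.6%, 43.6%, 48.2% and 48.9%. Without transcripts of size 5 or more they were 136 (CENPT), 212 (ERF), 167 (HOXA7), 247 (KDM5B), 92 (NR1H3), 129 (RUNX1T1) and 124 (STAT5B), and 978 for FOXF1, within 1.5 times. At an adjusted p under 0.01 they were 933 for FOXF1 and 364 for KDM5B, and with the statistic divided by its spread 811 for FOXF1, both fewer by construction.

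Of 34 list calls, 20 passed with a correlation of 0.05, 31 with ranks, 23 of 32 with base mean of at least 100, and all 34 with gene totals, which called 54 lists in all. Without heptamer genes 33 passed, and the ribosomal protein list after NR1H3 knockdown did not (0.0509). Only carriers of the heptamer taken for each table were left out. For FOXF1, genes with the related GTCTTCA (z −20.06) or AGTCTTC (z −14.09) but without TGTCTTC stayed in, so its lists were not tested free of such sites. Transcripts called alike in at least 2 tables numbered 802, 503 at an adjusted p under 0.01 and 213 without those of size 5 or more. Of 177 named results, 89 stayed on the same side of the threshold with the wider SE and 175 with centring. By gene totals 115 stayed, 3 passed anew, all of RNA5-8SN2 with too small an SE, and 50 did not pass, 23 of them with fold and SE within 0.1 and only the adjustment different. The sign was the other way in 9 whose totals cannot be told from 0 (adjusted p at least 0.93), RPS17 after CENPT (0.46), RRM2 after ERF (0.34), RPS2 after HOXA7 (0.01), CENPL after KDM5B (−0.63), NR3C1 after NR1H3 (0.02), FOXO3 after RUNX1T1 (−0.32), UHRF1 (−0.69) and MCM3 (0.11) after FOXF1 and SMC4 after STAT5B (0.1), as other transcripts of the gene enter the sum. For the other changes the cause was not tested. HOXA7 had too few reads for a gene total to be tested, and low counts limit it and NR1H3.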

Other observations

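The tests of shared calls and of heptamers in this part were chosen after their results had been seen.

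Some called genes belong to none of the lists tested, and no test joins them to a shared theme. The guidance factor gene SEMA3C fell after ERF and SEMA3A after FOXF1 knockdown. MAMDC2, a secreted proteoglycan gene, rose by 1.60 ± 0.20 (adjusted p = 1.3e-13) after FOXF1 and by 0.91 ± 0.27 (adjusted p = 0.0455) after CENPT knockdown in the authors' deposited tables. EBPL rose by 1.93 ± 0.36 (adjusted p = 1.2e-05) after KDM5B as well as by 2.14 ± 0.41 after STAT5B knockdown. GPR37, a receptor gene, rose by 1.38 ± 0.30 (adjusted p = 3.5e-04) and ZMIZ1, a coactivator gene, by 1.35 ± 0.31 (adjusted p = 0.0012) after KDM5B knockdown. After FOXF1 knockdown the hexosamine enzyme gene GFPT2 rose by 1.35 ± 0.30 (adjusted p = 3.8e-04), the small heat shock protein gene HSPB8 by 1.43 ± 0.34 (adjusted p = 0.0011), and ME2, mitochondrial malic enzyme, fell by 2.1 ± 0.19 (adjusted p = 1.2e-24).

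Genes whose 3′ UTR carries certain heptamers of the mRNA the siRNA was made against had lower log2 fold changes than others by regression, which may mark action of the siRNA guide through its seed on other messages. The lowest z among heptamers of the own target was −9.39 for CENPT (GAGAGGA), −9.32 for ERF (ATCAGTG), −17.16 for FOXF1 (TGTCTTC), −5.86 for HOXA7 (AGGACGA), −7.15 for KDM5B (GACTTAT), −6.66 for NR1H3 (AAACTGG), −7.16 for RUNX1T1 (ATCCCAT) and −5.42 for STAT5B (TTACCTT), where 1 simulated table without a planted heptamer gave −3.99. In that table the fold changes were shuffled over genes, which removes any link to the UTR, so it is a lenient reference. In 6 of 8 tables this was the lowest z of all heptamers. The own mRNAs held from 1763 of the 15980 heptamers tested (HOXA7) to 8000 of 16013 (KDM5B), so some of the 6 could arise by chance. In FOXF1 and NR1H3 a heptamer absent from the own target lay lower, GTCTTCA (−20.06) and AACTGGA (−7.16). Each is the own heptamer shifted by 1 base, with GTCTTC and AACTGG in common, so it is no separate signal. The HOXA7 and KDM5B mRNAs hold GTCTTCA, and the ERF and KDM5B mRNAs hold AACTGGA. Most own heptamers occur in other target mRNAs too. GAGAGGA lies in those of ERF, KDM5B, NR1H3, RUNX1T1 and STAT5B, ATCAGTG in KDM5B and STAT5B, and TGTCTTC in at least CENPT, ERF and RUNX1T1. AGGACGA lies in CENPT, GACTTAT in RUNX1T1, AAACTGG in at least RUNX1T1, and TTACCTT in KDM5B, while ATCCCAT lies in RUNX1T1 only. Presence in the own mRNA is thus weak evidence of a link to the siRNA. For NR1H3 the median log2 fold change was −0.03 both with and without AAACTGG. Pairing each table with its own target gave a sum of −68.12, and 21 of the 40320 pairings of tables and targets gave a sum as low, down to −70.73 (exact permutation p = 5.2e-04), which is consistent with such action. Length, base composition or repeats of the UTR argue for heptamers that stand as far out on the positive side, and in 8 of 8 tables the own heptamer stood further out than the most positive one after regression on them. The margin was small for KDM5B (most positive z 6.34), RUNX1T1 (6.03), NR1H3 (5.02), STAT5B (4.81) and HOXA7 (4.28). It was wider for CENPT (4.12), ERF (3.81) and FOXF1 (4.55). Of genes searched that were called lower, 39% carried the heptamer after CENPT, 53.5% after ERF, 50.1% after FOXF1, 9.52% after HOXA7, 18.2% after KDM5B, 12.5% after NR1H3, 34.4% after RUNX1T1 and 37% after STAT5B knockdown. Of all genes searched it was 16.8%, 14.1%, 19.8%, 2.1%, 7.72%, 18%, 10.6% and 16.8% in the same order, so NR1H3 shows no excess. Of genes called higher it was 14.3%, 13.8%, 7.35%, 0%, 1.43%, 16.7%, 22.6% and 11.1%, and the 22.6% for RUNX1T1 (7 of 31) lies above the share of all genes, which goes against a mark of lowering alone. These shares restate the choice of the heptamer, which was made by the falls of the same table, and add no support. An effect of the target and one of the siRNA were not separated gene by gene, which would need a second siRNA or the guide sequence.

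Transcripts called at a log2 fold change of 5 or more in size made up 2862 calls over the 8 tables, and such calls were shared more often by knockdowns with the same control. On average 2 tables with the same control shared 13.5% of these calls in direction and 2 with different controls 1.14%, a difference of 12.4 points, where the highest of the other splits of the 8 tables gave 2.26 (1 of 35 splits, exact permutation p = 0.03). This suggests that the state of the shared control libraries sets part of them. Reads given to another transcript of the same gene may account for others, as 68.8% of the 2713 with a gene name had a gene total that moved by less than 0.5. A change of isoform use by the knockdown cannot be told apart from chance assignment of reads for the 48.7% not seen in another table of the same control, because no values per library or junction reads were analysed here.

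STAT5B mRNA, with the heptamer ATCAGTG in its 3′ UTR, was the 1 targeted gene called in another knockdown, after ERF (control mean 460, knockdown mean 237 normalised reads). As a gene total its fall was the same (−0.96 ± 0.29) and its adjusted p 0.1, as only the adjustment differs. ARL5B carried the heptamer of each of the 3 knockdowns in which it fell, ERF, KDM5B (−0.52 ± 0.14) and STAT5B.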
